A study of Mus musculus with 12 samples.

How the data were processed

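The series holds 12 ChIP-seq samples of mouse embryonic stem cells, with 3 ESRRB ChIP and 3 input libraries from each of the lines NanogKO:Esrrb and NanogKO:Esrrb:Nanog. Per the labels' protocols, cells grew in serum with leukaemia inhibitory factor without treatment, and chromatin was fixed with formaldehyde alone or with a second fixation by di(N-succinimidyl) glutarate. Which fixation a sample had is not given in the sources used here, and neither is how Nanog was restored. Samples were grouped by their titles.

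The deposited count table gives whole-number read counts per region for the 6 ChIP libraries, unnormalised. Its 86201 regions are exactly the merged regions of the deposited peak lists, which was checked for every row. The submitters' processing notes name bcl2fastq 2.19.1, Bowtie2, SAMtools 1.4.1, deepTools, MACS2, bedtools 2.26.0 and mm10. Their order and settings, the peak threshold, the read counter and any removal of duplicate reads are not given in the sources used here. The deposited peak lists hold a chromosome, a start and an end, with no score, and their labels read as peaks shared by the 3 replicates of a line. Input libraries were not used here, because the table analysed has no input column, so the planned test of ChIP over input was not run. Columns of the table carry letters A, B and C and not the replicate numbers of the titles, so a column was matched to its line and not to a sample.

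Counts in regions ranged from 2734338 to 8382646 per library, so regions are measured with less counting error with Nanog than without. No pair of libraries of a line was a duplicate, with a chi-square per degree of freedom between 1.33 and 2.53. Regions were kept by filterByExpr of edgeR with the line as group, which left 84892 and removed 1309. Libraries were scaled by TMM, and each region was tested by glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled, and log-CPM has a prior count of 2. The design had the line alone, with no block.

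Each region was assigned to the nearest protein-coding gene of the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. The gene table gives start and end without strand, so distance was taken to the gene's span in place of the transcription start that had been planned, with 0 inside the gene. For the same reason the distance of 1 kb that was planned for promoters was taken to either end of a gene. Sequence motifs and GC content were planned and not analysed, because no genome was used here. Coordinates are 1-based.

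There were 14 gene lists fixed before the data were examined: naive pluripotency, general pluripotency, formative and primed epiblast, primitive endoderm, trophoblast, mesendoderm, neuroectoderm, FGF and ERK, LIF and STAT3, WNT, 2-cell-like, mitochondrial energy metabolism, housekeeping and fibroblast. A list's regions are those whose nearest gene belongs to it and lies within 50 kb. Lists were tested by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. They were also tested by fry, by which the naive pluripotency and mesendoderm lists alone were under the threshold in the test of a shift 1 way. In its mixed test, which takes changes in either direction, all 14 lists were under the threshold (fry, adjusted p from 4.32e-05 to 0.000362). The mixed test therefore does not set any list apart.

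Regions were named by a rule written before the data were examined. It takes the 12 largest increases and the 12 largest decreases among called regions with a mean log-CPM at or above the median and no overlap between the libraries of the lines, with 1 region per gene within 100 kb. It also takes, in each list, up to 4 genes by adjusted p at the region with the highest mean log-CPM of the gene, here called its strongest region. The strongest regions of Esrrb, Nanog, Klf4, Tfcp2l1, Tbx3, Pou5f1, Sox2, Otx2, Gata6, Gata4, Pdgfra, Sox17, Cdx2, Actb and Gapdh were taken in any case. The text gives part of them in full. A strongest region does not stand for the other regions of its gene, some of which were called the other way.

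Peak lists were compared with bedtools 2.31.1, counting a peak as shared from 1 bp of overlap. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other count filters, an offset by loess on signal, autosomes alone, leaving out each library, other distances and other overlaps. A block by column letter, libraries thinned to equal totals and the removal of mitochondrial regions were added after seeing the data.

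The tests were tested on simulated data drawn from the means and sizes of these libraries over 84892 regions, 200 of them changed. For the comparison with against without Nanog, edgeR called 2 of 67 regions changed 1.5-fold, 36 of 67 changed 2-fold and 65 of 66 changed 4-fold, and 2 of 84692 unchanged regions. With 200 changed regions, the adjusted threshold was stricter than in the data, where 16303 regions were called. These shares therefore do not give the sensitivity in the data. On the same regions, camera with its preset correlation called 5 of 5 random lists of 60 regions shifted 1.3-fold and 0 of 15 others. Regions were drawn independently there, so this does not test camera on lists whose regions are correlated, as those around a gene can be. Python 3.11.15 with SciPy 1.17.1 was used for Fisher's exact tests.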

Results

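ESRRB binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic stem cells grown in serum with leukaemia inhibitory factor. ESRRB is an orphan nuclear receptor of the pluripotency network, and NANOG is a homeodomain transcription factor of the same network. The labels name a Nanog-null line with ESRRB (NanogKO:Esrrb, "without Nanog" in what follows) and the same with Nanog (NanogKO:Esrrb:Nanog, "with Nanog"). Each line had 3 ESRRB ChIP libraries, and their counts in 86201 regions were compared. Counts in regions summed to 2734338, 3600055 and 5193707 in the libraries A, B and C without Nanog, and to 6689166, 8382646 and 7834773 with Nanog. The median count per region was 18, 24 and 34 without Nanog and 44, 56 and 51 with Nanog. The counts measure ESRRB and not NANOG, so they do not check the Nanog labels. The labels do not say whether the libraries of a line came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

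The first comparison asked where ESRRB signal differed with Nanog. Of 84892 regions tested, 7997 were higher and 8306 lower with Nanog (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold differences were found in 3720 of the higher and 1773 of the lower regions. The median log2 fold change was 0.96 among the higher regions, with quartiles of 0.72 and 1.26, and -0.79 among the lower regions, with quartiles of -0.96 and -0.62. The first principal component held 49.1% of the variance of log-CPM and separated the lines. The second held 22.7% and spread the libraries without Nanog, from -103 in B to 73.8 in A, against -6.32 to 14.6 with Nanog. Pearson correlations of log-CPM across regions, which are not independent, were 0.88 to 0.91 within the line without Nanog and 0.957 to 0.965 within the line with Nanog, against 0.836 to 0.883 between the lines. Fold changes are relative to the other regions, since library totals outside the regions were not used here and a change in ESRRB binding at all regions at once would not be seen. For the same reason the balance turned with the scaling, with 8998 higher and 7170 lower by column totals and 7100 and 9571 by TMM on the regions of lowest count. Leaving out library B with Nanog lowered the counts to 4988 higher and 4780 lower, and leaving out library A with Nanog lowered the count of lower regions to 5045.

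**Figure D1:**
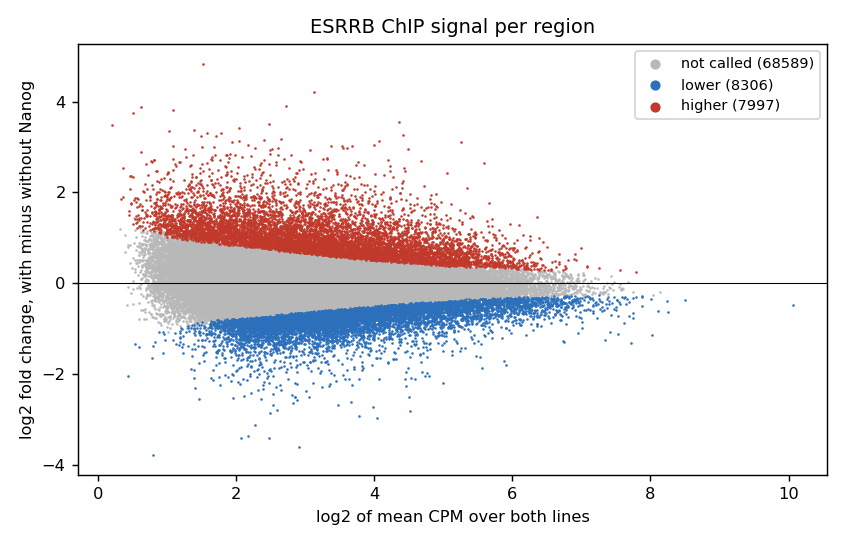
Each point is a tested region, with the log2 of its mean CPM over both lines on the x axis and its log2 fold change, with minus without Nanog, on the y axis. The 7997 regions higher with Nanog are red, the 8306 lower are blue and the regions not called are grey.

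Among called regions at or above the median signal whose libraries did not overlap between the lines, the 12 with the largest increase, 1 per gene, ranged up to a log2 fold change of 4.21 ± 0.33 (SE). The largest, a region at 104944724 to 104945112 on chromosome 11 (mm10), inside Gm11639, went from 0.86 ± 0.12 to 16.7 ± 2.2 CPM (SD, n = 3 per line, as for all CPM values here). A region inside Elmo1, which encodes a regulator of RAC signalling, at 20123974 to 20124373 on chromosome 13, went from 0.85 ± 0.27 to 12.3 ± 0.32 CPM. Signal inside Ncam1, a neural cell adhesion molecule, on chromosome 9 at 49653718 to 49654346, rose from 4.15 ± 1.4 to 38.7 ± 6.0 CPM. Hmga2, a chromatin architectural protein, held an increase from 1.23 ± 0.65 to 11.4 ± 2.5 CPM at 120388486 to 120388909 on chromosome 10. The region with the smallest adjusted p of these 12, 7.44e-14 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, lay 4.4 kb from Dstyk and rose from 7.76 ± 0.92 to 68.5 ± 5.2 CPM. The others were at Poli, Adamts8, Cpne4, Vps41, Tmem178b, Btbd11 and Nudcd2, with log2 fold changes from 2.96 at Nudcd2 to 3.55 at Poli.

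The 12 largest decreases were taken by the same rule. On chromosome 10 at 70854990 to 70855744, 67.5 kb from Bicc1, an RNA-binding protein gene, signal fell from 29.0 ± 7.9 to 3.76 ± 0.82 CPM, a log2 fold change of -2.98 ± 0.23. A region inside Knop1 on chromosome 7, at 118848795 to 118849458, fell from 52.6 ± 7.3 to 11.5 ± 2.2 CPM. The region 91.0 kb from Ctso fell from 40.3 ± 10.5 to 5.82 ± 0.15 CPM. Regions near or inside Sdr9c7, Pde4dip, Lypd6, Zfp809, Arhgap26, Elfn1, Kcna6, Gpr139 and Ripk4 had log2 fold changes from -2.72 at Sdr9c7 to -2.21 at Ripk4. Assignment to a gene is by distance and does not say that a region acts on it.

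The second comparison took lists of genes fixed before the data were examined, with the regions inside or within 50 kb of each gene. By camera with its preset correlation, regions at naive pluripotency genes were higher with Nanog more than other regions were. This call was lost with an estimated correlation and with 1 region per gene. Of 222 regions at 15 genes, 42 were higher, 7 lower and 173 not called, or 46 higher and 10 lower when adjusted over the list alone. The mean log2 fold change was 0.28 and the median 0.26 (camera, Benjamini-Hochberg adjusted p = 0.000146), with adjusted p = 0.525 with an estimated correlation between regions and adjusted p = 0.526 with 1 region per gene. It was the only one of 14 lists past the threshold with camera, and none was past it with an estimated correlation. Among its genes, 9 had only higher calls, 5 had both kinds and none had only lower calls.

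Klf4, a transcription factor of naive pluripotency, had its strongest region 49.6 kb away, on chromosome 4 at 55476821 to 55478195. Signal there rose from 34.6 ± 3.4 to 72.6 ± 3.1 CPM, a log2 fold change of 1.07 ± 0.12 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.61e-07). Of the 12 regions of Klf4 within 50 kb, this alone was called. Tcl1, a co-activator of AKT, rose from 23.5 ± 4.1 to 42.0 ± 2.5 CPM at its strongest region. The strongest region of Nanog itself, 4.7 kb outside the gene on chromosome 6 at 122702238 to 122703301, held 64.3 ± 10.2 CPM without and 83.0 ± 1.1 CPM with Nanog (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0223). That of Klf5 held 95.2 ± 4.8 and 76.8 ± 5.7 CPM (adjusted p = 0.0388 by the same edgeR test with Benjamini-Hochberg adjustment). Both calls were lost with DESeq2 and on leaving out any library but B without Nanog, with log2 fold changes of 0.29 to 0.52 at Nanog and -0.36 to -0.25 at Klf5 over the libraries left out. The strongest regions of Esrrb, with 127 ± 17 and 133 ± 4.7 CPM, and of Tfcp2l1, with 112 CPM in both lines, were not called. Esrrb and Zfp42, chosen after their values were seen, held the most higher calls of the list, 9 of 33 regions and 8 of 18 regions, with 0 and 1 lower calls.

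**Figure D2:**
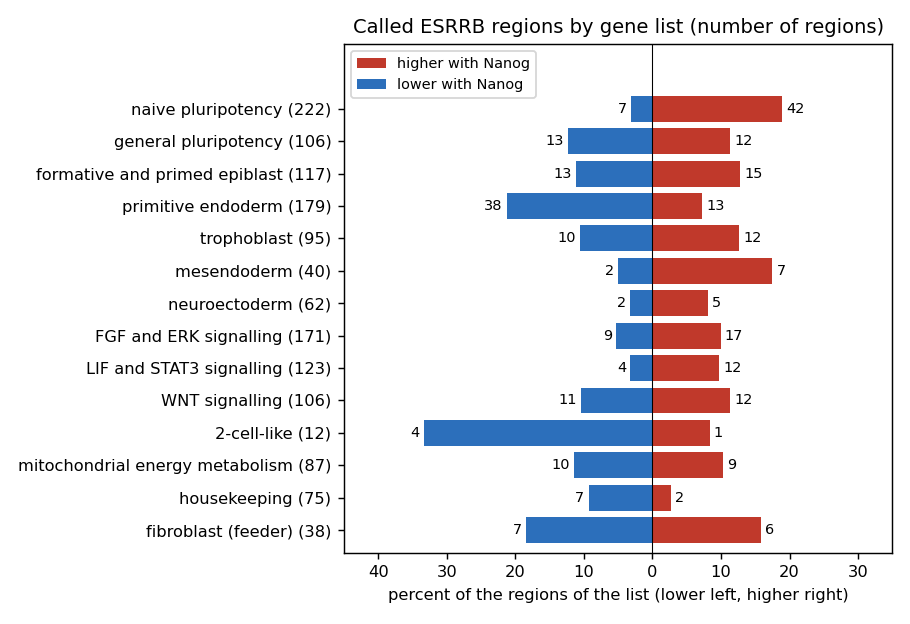
Bars give the percent of the regions of each gene list that were higher (red, right) or lower (blue, left) with Nanog, with the number of such regions at the bar and the number of regions in the list in brackets. The naive pluripotency list had 42 higher and 7 lower regions, and the primitive endoderm list 13 higher and 38 lower.

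Primitive endoderm genes, markers of the extraembryonic lineage that NANOG is known to oppose, held more lower than higher calls. Of 179 regions at 19 genes, 13 were higher and 38 lower, or 16 and 42 when adjusted over the list alone, with a mean log2 fold change of -0.13. The list did not pass camera (adjusted p = 0.149, and adjusted p = 0.657 with an estimated correlation). Without library B of the line without Nanog its mean was -0.03, and with 1 region per gene it was 0.01. Fgfr2, an FGF receptor, held 9 lower and 2 higher calls among 22 regions. Amn, part of the cubilin receptor complex, fell from 48.9 ± 15.7 to 28.4 ± 0.75 CPM, Dkk1, a secreted WNT antagonist, from 20.8 ± 8.4 to 10.0 ± 2.2 CPM, and Sparc, a matrix protein, from 46.6 ± 1.8 to 31.7 ± 3.6 CPM at their strongest regions. The strongest regions of Gata6, Gata4, Sox17 and Pdgfra were not called, with log2 fold changes of 0.06, 0.16, -0.05 and -0.31.

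**Figure D3:**
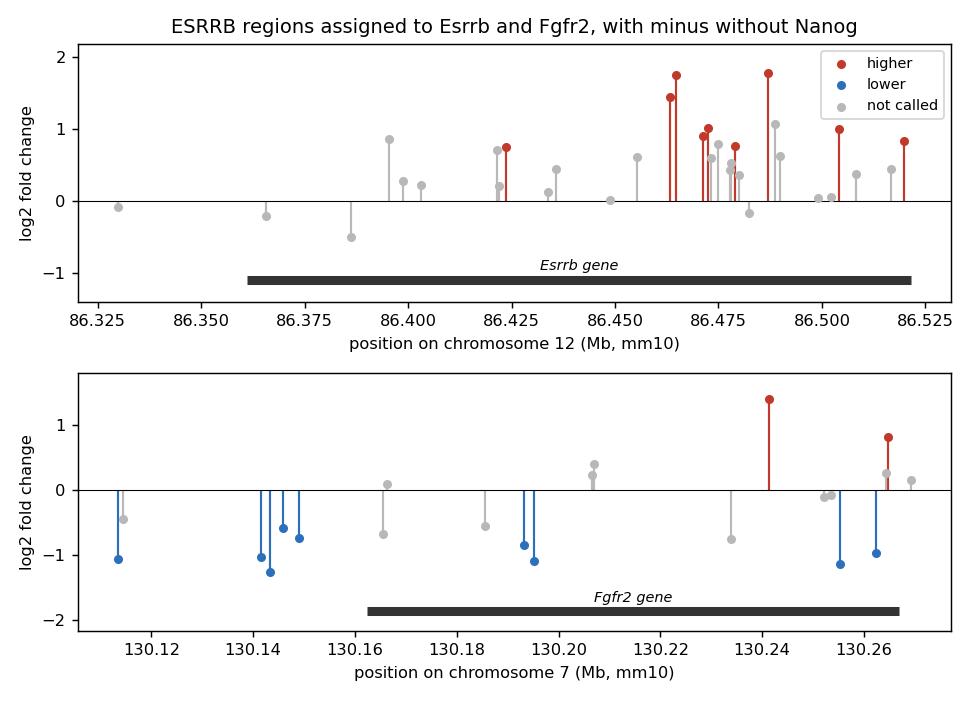
Each line is a region assigned to Esrrb (top, 33 regions) or Fgfr2 (bottom, 22 regions), at its position in Mb (mm10) and with its log2 fold change, with minus without Nanog, coloured by call, above a bar for the annotated gene. Both genes were chosen after their values were seen, with 9 higher calls at Esrrb and 9 lower calls at Fgfr2.

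Formative and primed epiblast genes went both ways, with 15 higher and 13 lower calls among 117 regions (camera adjusted p = 0.804; 15 and 15 adjusted over the list alone). Foxd3, a forkhead factor, rose from 13.4 ± 1.9 to 83.3 ± 12.1 CPM 19.8 kb from the gene, at 99635842 to 99637114 on chromosome 4, a log2 fold change of 2.65 ± 0.15. Tcf15, a basic helix-loop-helix factor of the epiblast, fell from 371 ± 36 to 238 ± 13 CPM. Pou3f1, a POU factor, fell from 48.5 ± 2.5 to 29.2 ± 1.7 CPM, and Dnmt3a, a de novo DNA methyltransferase, from 78.8 ± 16.2 to 53.5 ± 1.5 CPM. General pluripotency genes held 12 higher and 13 lower calls among 106 regions (adjusted p = 0.918; 12 and 13 adjusted over the list alone), and the strongest regions of Pou5f1 and Sox2 were not called, with log2 fold changes of 0.19 and -0.25.

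Trophoblast genes held 12 higher and 10 lower calls among 95 regions (camera adjusted p = 0.725; 13 and 10 adjusted over the list alone). Bmp4, a secreted ligand, rose from 7.03 ± 0.60 to 22.2 ± 3.1 CPM, and Elf5, an ETS factor, from 4.96 ± 1.9 to 16.8 ± 4.7 CPM. Cdx2, a trophectoderm homeobox factor, fell from 60.3 ± 10.4 to 40.3 ± 1.3 CPM, and Ets2 from 47.2 ± 0.77 to 25.9 ± 3.7 CPM. Mesendoderm genes held 7 higher and 2 lower calls among 40 regions (camera adjusted p = 0.149; 7 and 2 adjusted over the list alone). By fry, which asks whether a list moves on balance one way, this list and the naive list both had adjusted p = 0.0452. Neuroectoderm genes held 5 and 2 among 62 (adjusted p = 0.725; 5 and 1 over the list alone), with Pax6, a paired-box factor, rising from 22.8 ± 1.3 to 63.2 ± 1.3 CPM.

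Signalling lists did not pass camera either. FGF and ERK genes had 17 higher and 9 lower calls among 171 regions (adjusted p = 0.472; 16 and 9 adjusted over the list alone), and LIF and STAT3 genes 12 and 4 among 123 (adjusted p = 0.255; 7 and 4 over the list alone). WNT genes had 12 and 11 among 106 (adjusted p = 0.983; 12 and 11 over the list alone). Lrp6, a WNT co-receptor, fell from 34.7 ± 2.0 to 11.2 ± 0.27 CPM, and Ctnnb1, which encodes beta-catenin, from 19.3 ± 3.0 to 11.4 ± 0.74 CPM at their strongest regions. Etv4, an ETS factor downstream of FGF, fell from 106 ± 13 to 77 ± 1.0 CPM at its strongest region. Higher calls were made at the strongest regions of Grb2, an adaptor of receptor signalling, Pim1, a kinase gene, and Stat3, with log2 fold changes of 0.51, 0.41 and 0.71. With libraries left out these ranged over 0.35 to 0.62, 0.36 to 0.51 and 0.49 to 0.93, and each call was lost in some of these fits, those of Grb2 and Stat3 also with DESeq2. Over all its 6 regions, Stat3 had 1 higher and 2 lower calls. Pim1 had 5 and 1 among 22 regions, and Grb2 had 2 and 0 among 7. Lrp6, Ctnnb1 and Etv4 each had 1 higher and 1 lower call, so these genes did not move 1 way.

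Mitochondrial energy genes, which related receptors are known to regulate, had 9 higher and 10 lower calls among 87 regions (camera adjusted p = 0.918; 9 and 10 adjusted over the list alone). Esrra, a related receptor, fell from 114 ± 15 to 84.0 ± 6.6 CPM, and Sdhb, a succinate dehydrogenase subunit, from 93.3 ± 9.6 to 67.5 ± 6.2 CPM. Housekeeping genes had 2 higher and 7 lower calls among 75 regions (adjusted p = 0.377; 2 and 6 over the list alone), and the strongest regions of Pgk1, Hprt, Ppia and Rplp0 were called lower, with log2 fold changes of -0.98, -0.94, -0.42 and -0.55. With libraries left out these ranged over -1.40 to -0.65, -1.14 to -0.76, -0.49 to -0.32 and -0.67 to -0.27. The calls at Pgk1 and Rplp0 were lost with DESeq2, and those at Hprt, Ppia and Rplp0 on leaving out some libraries. The strongest regions of Actb and Gapdh were not called, with log2 fold changes of 0.21 and -0.19 (0.03 for Gapdh with a loess offset). Genes of 2-cell-like cells had 1 and 4 among 12 (adjusted p = 0.136; 1 and 5 over the list alone). Fibroblast genes, included because feeder cells can be present in such cultures, had 6 and 7 among 38 (adjusted p = 0.918; 7 and 8 over the list alone).

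**Figure D4:**
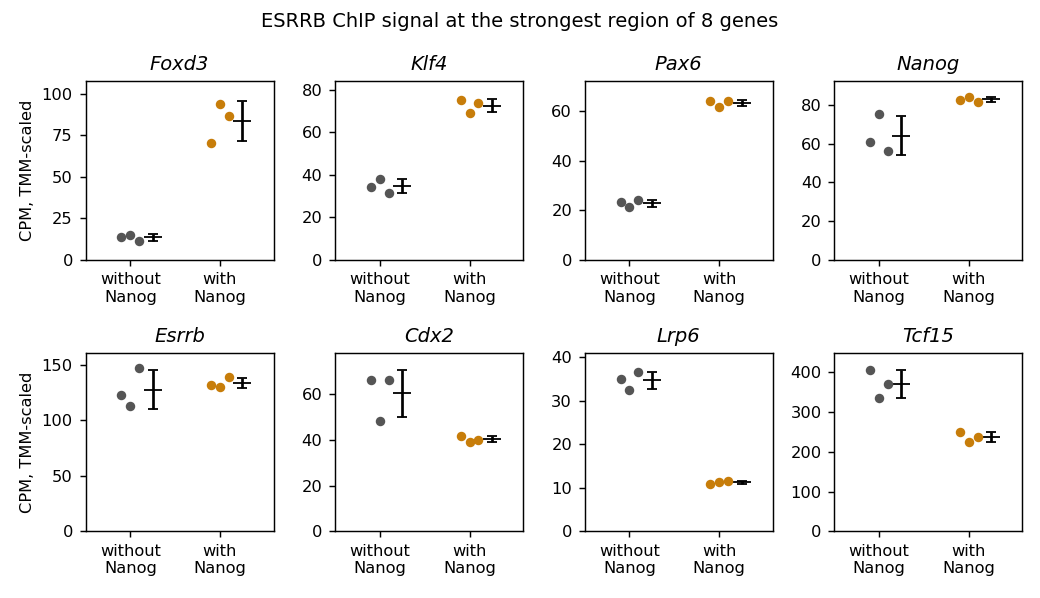
Points are the TMM-scaled CPM of each library at the region with the highest mean log-CPM of 8 genes, and bars give the mean and SD of 3 libraries per line. Foxd3, Klf4, Pax6 and Nanog were higher with Nanog, Cdx2, Lrp6 and Tcf15 were lower, and Esrrb was not called.

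Changed regions lay near gene ends less often than regions not called. The centre lay within 1 kb of an annotated end of a protein-coding gene in 5.35% of the higher regions, 6.42% of the lower regions and 14.9% of the regions not called. Odds ratios against the regions not called were 0.323 for higher regions (Fisher's exact test, two-sided, p = 3.58e-148) and 0.391 for lower regions (p = 1.17e-116). Regions are not independent replicates, so these p-values are too small. Of the regions farther from gene ends, 52.9% of the higher, 41.5% of the lower and 50.8% of those not called lay inside a gene.

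The deposited peak lists differed in length, with 34956 peaks without and 85537 with Nanog. Of the peaks without Nanog, 34260 (98.0%) shared at least 1 bp with a peak of the other list, and of those with Nanog 32645 (38.2%) did. There is 1 list per line, so list lengths carry no replicate error. Among 51603 tested regions found in the list with Nanog alone, 5584 (10.8%) were higher, 992 lower and 45027 not called by edgeR. Of 32615 regions in both lists, 2413 were higher and 6778 lower with Nanog. Of 674 regions in the list without Nanog alone, 536 were lower and 138 not called. The lists were called on the same libraries as the counts, so list membership is not independent of the direction of the call. Regions in the list with Nanog alone had a median of 4.56 CPM without and 4.68 CPM with Nanog, with no input here to set this against background.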

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

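All alternatives were planned except the letter block, the thinning and the removal of mitochondrial regions, which were added after seeing the data. In 11 of 19 alternatives all 16303 called regions kept their sign, and the other 8 did not test all of them. Against 7997 higher and 8306 lower regions, DESeq2 gave 4785 and 5461, a mean count of at least 50 gave 4978 and 5503 from 33017 regions tested, and thinning to equal totals gave 5178 and 4907 with fewer reads. Leaving out 1 library gave 4988 to 9288 higher and 4780 to 8971 lower, the lowest without library B with Nanog. At least 2-fold changes numbered 2383 higher with DESeq2, and 1234 higher and 534 lower at a mean count of at least 50. No gene list (0) was called with 1 region per gene or with an estimated correlation, and the naive pluripotency list held in the 11 other alternatives, with adjusted p from 3.89e-05 to 0.00279. Shared peaks moved to 68.7% and 28.1% with reciprocal 50% overlap and to 87.2% and 35.6% with centres within 200 bp, and to 97.2% without Nanog in the wider peaks of each list. Some named regions not called changed sign in at least 1 alternative. With 1 library left out, log2 fold changes ran from -0.015 to 0.193 at Esrrb, -0.033 to 0.085 at Tfcp2l1, -0.21 to 0.072 at Otx2, -0.027 to 0.264 at Gata6, -0.07 to 0.366 at Gata4 and -0.206 to 0.087 at Sox17. Tfcp2l1 was at -0.04 with TMM on the lowest part of the signal, Otx2 at 0.017 and Gapdh at 0.027 with the loess offset, and Sox17 at 0.048 after thinning. Of 68 named calls, 21 were lost in at least 1 alternative and 0 reversed, and of 22 named regions not called 8 gained a call in at least 1. The cause of these moves was not tested beyond the fewer reads, regions or libraries named. The letters were not taken as pairs, because no label says what a letter marks. Same-letter libraries had deviation correlations of 0.08, 0.22 and 0.13, against -0.16 to 0.04 for unlike letters across the lines. Each library correlated best with its own letter, a hint of pairing from the data. A replicate block by letter gave 10095 higher and 10825 lower. Not run were the block by replicate number, GC offsets, motif settings and ChIP over input, for want of numbers, a genome and input columns. Small changes were mostly missed in simulated data, with 2 of 67 regions changed 1.5-fold recovered. Only 200 of 84892 regions were changed there, so the adjusted threshold was stricter than in the data, with 16303 calls. This share therefore does not give the sensitivity in the data.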

Other observations

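The thinned replicate correlation, the trend with signal in regions of both lists and the flanks of runs were tests fixed before their results were seen, and the other tests here were chosen after. That the tests of depth, enrichment, gain and mitochondrial DNA leave these open was also settled after their values were seen, for the reasons given with each. Some called regions lay in runs along the genome, and how many runs would arise by chance was not tested. There were 95 runs of at least 4 neighbouring tested regions that were all called in 1 direction, 57 higher and 38 lower with Nanog, all chosen after their values were seen. With Klf4 as the nearest gene, 7 regions between 55462790 and 55478195 on chromosome 4 were higher, with a median log2 fold change of 0.95. The closest of them lay 49.6 kb from Klf4 and was the only call among the 12 regions of the gene within 50 kb. A run of 7 inside Mras, a RAS-related GTPase gene, between 99414874 and 99425372 on chromosome 9, was higher with a median of 1.92. With Eomes, a T-box factor, as the nearest gene, 8 regions between 118391844 and 118401407 on chromosome 9 were lower, with a median of -1.02. The 12 regions within 50 kb of Eomes held 1 higher and 2 lower calls, so most of this run lay farther away. Around the region 67.5 kb from Bicc1, 7 regions between 70846187 and 70857531 on chromosome 10 were lower, with a median of -2.52. The run with the most regions, 9 lower inside Sfi1 on chromosome 11, had a median of -0.53.

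Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls as the real 16303, the real one itself, and the highest other gave 0 (edgeR, the tool used). With 10 splits a share under 0.05 cannot be reached.

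Pairs of neighbouring called regions within 5 kb had the same direction in 86.1% of 1718 pairs, against 50.02% on average after shuffling. Regions that split a single binding site do not account for this alone, since pairs 5 to 20 kb apart still had the same direction in 67.1% of cases, above the highest of 1000 shuffles at 53.6%. A copy number difference over 200 kb or more on each side is argued against by the flanks of 94 nuclear runs, whose median log2 fold change in the direction of the run was 0.15 (quartiles 0.02 and 0.30), against 0.95 in the runs. Only 3 flanks reached 0.5, so shorter segments and these 3 stay open. A regional effect of Nanog on chromatin may be involved, which was not tested.

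The peak list with Nanog was longer by far, and depth, enrichment and a gain of binding cannot be told apart as its source. For lower depth, thinning all libraries to 2734338 counts reduced the gap in mean replicate correlation from 0.0629 to 0.0259. This was over the bound of 0.02 set beforehand but by less than the spread between pairs. After thinning, pairs ranged over 0.883 to 0.902 without and 0.912 to 0.921 with Nanog. No peaks were called at equal depth, and counts in regions depend on enrichment as well as depth. How much of the list length depth accounts for was therefore not tested. For lower enrichment, the strongest less the weakest regions gave 0.44 over regions in both lists, past the 0.2 set beforehand, but -0.24 over all regions, and each choice of regions is itself set by the peak lists. For a gain at most regions in the list with Nanog alone, their median log2 fold change lay 0.30 above that of regions in both lists, at most 0.33 with 1 library left out. Lower enrichment would hide a gain at weak regions, and a gain with Nanog at all regions at once would not be seen in scaled counts.

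The 4 mitochondrial regions were lower with Nanog, with log2 fold changes of -1.31 to -1.24. Raw counts there were nearly flat across libraries, between 2436 and 2974, a ratio of 1.22 where totals differed by 3.07. At 1.80 to 2.20 reads per bp, a cap from removal of duplicate reads is a candidate explanation, and the scaled decrease would then follow from library totals. More mitochondrial DNA without Nanog cannot be told apart, because a capped count does not record it: counts there differed by a ratio of 1.02 among the libraries without Nanog while totals differed by 1.90.

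A hypothesis is that ESRRB signal may shift with Nanog from primitive endoderm to naive pluripotency genes. The mean log2 fold change per gene was 0.25 ± 0.21 (SD) over 15 naive genes and -0.10 ± 0.37 over 19 primitive endoderm genes, a difference of 0.35 (two-sided permutation test across genes with 100000 resamples, p = 0.00252). It was above 0 in 14 of the naive and 5 of the primitive endoderm genes. Genes are not independent replicates and the pair of lists was chosen after seeing their counts. Over regions, leaving out library B of the line without Nanog gave means of 0.33 and -0.03, and 1 region per gene gave 0.17 and 0.01, so the primitive endoderm side depends on that library and on the weaker regions. Across libraries, the mean log-CPM of naive less primitive endoderm regions was 0.02 to 0.13 without and 0.41 to 0.53 with Nanog (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows).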
